A study of Mus musculus with 4 samples.

How the data were processed

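Single-cell RNA was measured in 4 treatment arms. Each arm pooled 5 tumours into 1 library by the 10x Genomics droplet method, per the labels' protocols. The labels call the first arm vehicle control in the treatment protocol and untreated in the sample's own entry, and it is called vehicle here. The submitters' processing notes name Cell Ranger, Seurat and genome build mm10, without versions, parameters or filters on cells. The deposited table joins the libraries, with 13518 genes and 13213 cells, and a cell's library was read from its column name. Of the cell barcodes, 1 is found in 2 libraries.

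The deposited values are on a natural log scale. Across each cell's non-zero values, 1 constant per library turns every value into a whole number of UMIs. The authors' values are therefore read as the natural log of 1 plus the UMIs per 10000 UMIs of the cell, lowered by a library constant, with values under 0 set to 0. The constant was 0.247 in vehicle, 0.249 in anti-PD-1, 0.153 in ATT-I and 0.225 in the combination, and no label gives its reason. With it, 100% of the non-zero values in each library came out within 0.02 of a whole UMI. The subtraction sets genes with 1 UMI to 0 in the deepest cells, which affected 21 vehicle, 37 anti-PD-1, 0 ATT-I and 37 combination cells. These cells were kept. The median cell held 16118 UMIs in vehicle, 7146.5 in anti-PD-1, 6826 in ATT-I and 23910 in the combination. At 155, 12562, 297 and 199 cells, the exact 95% interval of the share of each named class is widest in vehicle.

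Cells of all libraries were clustered together with scanpy 1.11.5 in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19), without batch correction. The steps were 2000 variable genes, scaling, 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 through igraph 0.11.9. Genes of the fixed lists and mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor variable genes were left out of clustering. The lowest number of genes in a cell was 593, so a filter of 500 genes removes no cell. Scrublet, run through scanpy on each library, called 6 vehicle, 0 anti-PD-1, 4 ATT-I and 5 combination cells doublets. It made no call among 12562 anti-PD-1 cells and so did not work there, and no cell was removed.

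Each of the 15 clusters was scored for CD8, CD4 conventional, regulatory T and NK cells. Markers of a gamma-delta T cell class had also been fixed, but that class was not scored. The score is the mean over a class's markers, without Cd3e, of the cluster's level divided by the highest cluster's level. A class names a cluster when its score is highest, at least 0.5 and at least 0.25 above the next class, and 3 of its markers are each found in over 10% of cells. No other class may have more markers among the cluster's 10 leading genes, which are the genes in at least 25% of its cells with the highest ratio to all other cells. A cluster with Cd3e in under 60% of cells can only be NK cell-like. T cell-like clusters have Cd3e in at least 60% of cells, 3 T cell markers detected, and no more NK than T cell markers among the leading genes. This leaves out clusters 1, 6 and 8. The marker lists, gene lists, comparisons, rule for named genes and first set of alternatives were fixed before the data were examined. The naming thresholds were not. They were set after cluster markers had been seen, in 2 versions, and the first, without the margin and the condition on leading genes, is kept as an alternative.

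Tumour-like and monocyte or macrophage-like cells had been chosen for the main lists, but no cluster was led by a set of their markers. Of single markers, Areg (tumour) was among the leading genes of regulatory cluster 14 and Ly6c2 (monocyte) among those of CD8 cluster 5. Comparisons in tumour-like and monocyte or macrophage-like cells are therefore not made here. The checkpoint ligand, hypoxia, unfolded protein, p53, matrix and myeloid lists meant for them are not analysed here. The class I antigen presentation, immunoproteasome, proteasome, interferon and proliferation lists were instead read in T cell-like cells, a choice made after the data were seen. Comparisons were ATT-I, anti-PD-1 and the combination against vehicle, and the combination against anti-PD-1 and against ATT-I. Each needs 50 cells in both libraries. Vehicle held 48 CD8 cells, so CD8 cells were compared only for the combination against each single treatment. Lists were not read in CD4 cells.

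A gene's level is the mean over cells of UMIs per 10000, and comparisons are log2 ratios of these means without a pseudocount. A gene enters where at least 10% of the cells of either library have a UMI. A library without any UMI takes a floor of 3 UMIs over the library. A list is summarised by its median log2 ratio and by the number of members at least 1.25-fold higher or lower. Its 95% range comes from 1000 Poisson redraws of the summed UMIs, and its percentile from 10000 random lists matched in 20 bins of expression. Ranges of single genes are exact binomial intervals for the ratio of summed UMIs, shifted to the log2 ratio of means that is reported. Both kinds of range treat UMIs as independent, so they are too narrow where a few cells hold most of a gene's UMIs. These ranges cover counting error, and 1 library per arm gives no estimate of differences between mice, tumours or libraries. Cells of 1 library are not replicates, so no test was run and no p-value is given.

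Named genes are the 3 members of each lymphocyte list with the largest absolute log2 ratio, always Cd8a, Gzmb, Prf1, Ifng and Pdcd1, and the 5 highest and 5 lowest genes outside the lists. The last leave out mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor and predicted genes. Il2ra and Tnfrsf18 are in both the activation and the regulatory T cell list, and Ctla4 is in both the exhaustion and the regulatory T cell list. Granzyme, histone, haemoglobin and Klra genes have close relatives, and Xist and Tsix overlap on opposite strands. How shared reads and strands were counted is not stated, so single members are uncertain. Symbols were matched to GENCODE mouse release 21 on GRCm38, the assembly of mm10, where 13389 of 13518 were found, and coordinates are 1-based.

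The steps were tested on simulated data for ATT-I against vehicle, with 219 and 136 cells, the numbers of T cell-like cells, and 200 of 13518 genes changed. Of the simulated values left above 0 once the constant was taken off, 100% were recovered as the simulated UMIs. Values that the constant set to 0 were not counted. Median log2 ratios were 1.01 for genes changed 2-fold, −0.98 for 0.5-fold, 1.98 for 4-fold and −1.91 for 0.25-fold. Of 7793 unchanged genes, 30.7% lay at or past 1.25-fold by counting noise.

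For the class shares, the first set of alternatives was Leiden resolutions of 0.5 and 2, 15 and 50 principal components, fixed-list genes kept for clustering, a class for each cell from its highest marker mean, at least 500 genes per cell, and doublets left out. For gene levels they were differences of mean natural log values, ratios of summed UMIs, cells thinned to 3000 UMIs with shallower cells left out, minimum shares of 0, 5% and 25%, totals without mitochondrial and ribosomal genes, centring on the median of all genes, and list means. A filter of 500 genes was planned for tumour-like cells and applied to T cells. Added after the data were seen were the first naming rule, all deposited cells, equal weight for each cluster with at least 5 cells in both libraries, clusters led by cell cycle genes left out (0, 2, 3, 11 and 12), doublets left out of gene levels, cells with 1-UMI values set to 0 left out, and cluster 13 or cluster 12 left out. In CD8 cells the equal weights left cluster 0 alone, so they do not balance cell states there. In T cell-like cells they kept clusters 0, 3 and 10 in each comparison. Cluster 12 was added for anti-PD-1 against vehicle. Cluster 7 was added for the combination against ATT-I, and clusters 7 and 13 for the combination against anti-PD-1. Cells of all other clusters were left out of those values. Explanations of 3 patterns were examined with proliferation genes in cells of 5000 to 15000 UMIs (and, added after the values were seen, above 15000, with the share of cycling cells each library kept in the window), haemoglobin in ATT-I clusters of at least 10 cells, and 56 histone genes. Figures were drawn with matplotlib 3.10.9.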

Results

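Single-cell RNA sequencing was run on tumours grown in C57BL/6 mice from orthotopically implanted MC38 cells, a mouse colon carcinoma line. The series asks how Atractylenolide I (ATT-I), a sesquiterpene lactone from Atractylodes rhizomes, bears on the response to PD-1 blockade and on tumour antigen presentation. There were 4 arms: vehicle control, anti-PD-1, ATT-I, and ATT-I with anti-PD-1 (the combination). Each arm gave 1 droplet library made from a pool of 5 tumours, taken 2 weeks after the first treatment. ATT-I was given daily at 50 mg/kg, and anti-PD-1 3 times a week for 5 doses. The table held 155 vehicle cells, 12562 anti-PD-1 cells, 297 ATT-I cells and 199 combination cells. Total depth was 3.05, 108.5, 2.88 and 5.15 × 10⁶ UMIs in that order. The median cell held 16118 UMIs in vehicle, 7146.5 in anti-PD-1, 6826 in ATT-I and 23910 in the combination. No arm has a replicate library, so every difference below compares 4 libraries and not 4 treatments. The 95% intervals and ranges cover counting error only.

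Clusters were named as T or NK cells from their leading genes and marker scores. Summed T cell markers averaged 59.5 UMIs per 10,000 in vehicle, 89.7 in anti-PD-1, 70.1 in ATT-I and 62.6 in the combination. Summed epithelial tumour markers, 9 of 13 measured, averaged 0.361, 1.17, 0.680 and 1.01 in the same order, and no cluster was led by a set of them. They include Areg, a leading gene of regulatory T cell cluster 14. Areg in T cell-like cells made up 6983 of their 10841 UMIs in anti-PD-1 and 490 of 566 in the combination, but 12 of 123 in vehicle. The sum is therefore no measure of tumour cells. Summed monocyte or macrophage markers averaged 9.53, 11.3, 6.80 and 9.88, above the NK markers at 4.56, 4.60, 2.69 and 2.95. The monocyte markers include Ly6c2, a leading gene of CD8 cluster 5. CD8 T cell-like cells made up 31.0% of vehicle cells (exact Clopper-Pearson 95% interval 23.8 to 38.9), 47.2% of anti-PD-1 cells (46.4 to 48.1), 27.3% of ATT-I cells (22.3 to 32.7) and 53.8% of combination cells (46.6 to 60.8). CD4 conventional T cell-like cells made up 36.1% in vehicle, 12.3% in anti-PD-1, 32.3% in ATT-I and 24.1% in the combination. The share of regulatory T cell-like cells lay between 11.8% in ATT-I and 16.8% in vehicle, with overlapping intervals in all 4 libraries. These shares came from different clusters. Cycling cluster 3 held all 26 such cells in vehicle, 25 of 28 in the combination, 21 of 35 in ATT-I and 376 of 1930 in anti-PD-1. Cluster 14 held the other 1554 in anti-PD-1 and 0 in vehicle. NK cell-like cells were 12 of 155 in vehicle (7.74%, 4.06 to 13.1), 59 of 12562 in anti-PD-1 (0.470%, 0.358 to 0.605), 5 of 297 in ATT-I (1.68%, 0.549 to 3.88) and 1 of 199 in the combination (0.503%, 0.0127 to 2.77). With fixed-list genes kept for clustering no cluster was named NK cell-like, giving 0% in each library. The anti-PD-1 share of CD8 cells depends on how cells are classed, and was 60.0% under the first naming rule and 71.7% when each cell took the class with its highest marker mean. Other shares moved too. By highest marker mean the regulatory shares were 24.5% in vehicle, 17.9% in anti-PD-1, 22.2% in ATT-I and 24.1% in the combination. The ATT-I share of CD4 cells ran from 19.2% to 44.4% over the alternatives.

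**Figure D1:**
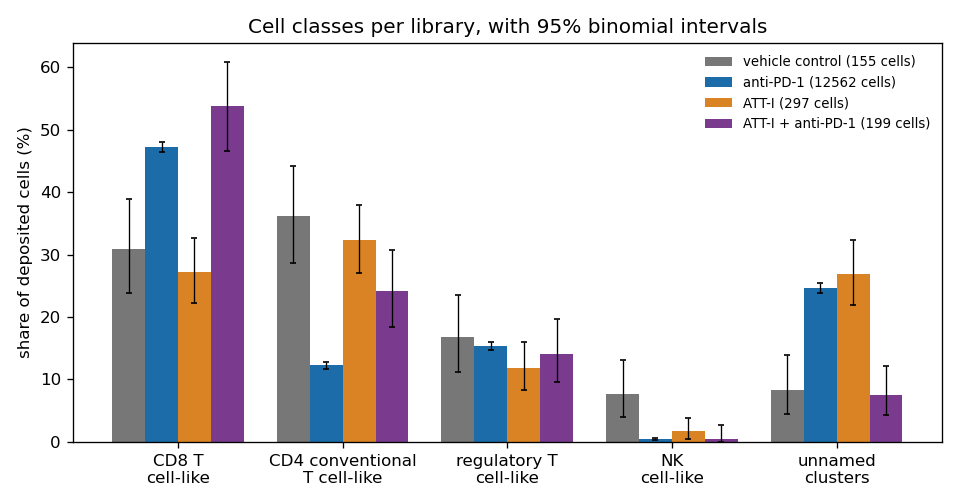
Share of the cells in each library (y axis, percent) that fell in each cell class (x axis), 1 bar per library, with exact 95% binomial intervals as error bars. The CD8 T cell-like bar stands at 53.8% in the combination library and 47.2% in anti-PD-1, with overlapping intervals and an order that changes with the classing, and the CD4 conventional bar is lowest in the anti-PD-1 library (12.3%).

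Within the CD8 class the cells of each library fell in different clusters. Clustering was without batch correction, so cell state cannot be told apart from depth or library here. The median cell held 16118 UMIs in cluster 0, and 5690, 5008 and 8013 in clusters 4, 5 and 9. Cluster 0, led by replication-dependent histone genes and cell cycle genes such as Ttk and Esco2, held 42 of the 48 CD8 cells in vehicle, 31 of the 81 in ATT-I and 95 of the 107 in the combination. Cluster 4, led by interferon-stimulated genes, held 19 CD8 cells in ATT-I and 3 in the combination, and cluster 5 held 15 and 2. In anti-PD-1 the 5933 CD8 cells were spread over cluster 9 (1801 cells), clusters 0 and 5 (1105 cells each), cluster 4 (917 cells) and cycling clusters 2 and 11 (626 and 379 cells). Cluster 9 held 0 of the 155 vehicle cells, with an exact 95% interval up to 2.35%. A further Cd8a-positive cluster, 8, was kept out of the class because Klri2, an NK receptor gene, was among its leading genes beside Gzmf and Ifitm1. Cd8a UMIs were found in 99.4% of its cells (median depth 6959 UMIs), against 37.4% in the CD4 cluster 10 (6763 UMIs), where free RNA can give them. Cluster 8 made up 12.7% of anti-PD-1 cells and 0.645% of vehicle, 1.68% of ATT-I and 0 of 199 combination cells, the last with an exact 95% interval up to 1.84%. Cluster 6, led by Klra receptor genes with Tcf7, a gene of less differentiated lymphocytes, made up 22.9% of ATT-I cells, 10.4% of anti-PD-1, 3.87% of vehicle and 2.51% of combination cells. Clusters 6, 8, 12 and 13 have no class name here, and their leading genes were read after the values were seen. Gene levels were compared over T cell-like cells, 136 in vehicle, 9599 in anti-PD-1, 219 in ATT-I and 193 in the combination. These leave out clusters 1, 6 and 8, though Cd3e was found in 91.3% of cluster 6 cells and 98.9% of cluster 8 cells. The cells kept were 87.7% of vehicle, 76.4% of anti-PD-1, 73.7% of ATT-I and 97.0% of combination cells, so the exclusion is unequal. The T cell-like cells keep cluster 12, whose leading genes include NK receptor genes such as Klra6 and Klrb1f and whose highest class score is that of NK cells, with 6 vehicle, 133 anti-PD-1, 3 ATT-I and 2 combination cells.

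All genes together shifted between libraries, so a second value relative to the median gene follows the median of each lymphocyte list and of the proliferation list in T cell-like cells. That median was −0.36 log2 for anti-PD-1 against vehicle, −0.35 for ATT-I against vehicle, −0.15 for the combination against vehicle, 0.17 for the combination against anti-PD-1 and 0.19 against ATT-I. A member of a list counts as higher or lower at 0.32 log2 or more. With 1 library per arm, a change of that size in a single low gene is within counting noise: 30.7% of unchanged genes passed it in a simulation of ATT-I against vehicle.

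The comparison of anti-PD-1 with vehicle asks what PD-1 blockade alone changes. Cytotoxic genes were higher in the anti-PD-1 library: 11 of 14 measured members were higher and 3 lower, with a median of 1.61 log2 (95% counting range 1.58 to 1.67; 1.97 relative to all genes), above all 10000 random lists of matched expression. Gzmb, the granzyme B protease (chromosome 14, 56258838 to 56262260 in GRCm38), was higher by 1.59 (1.52 to 1.66). Prf1, the pore-forming protein perforin (chromosome 10, 61297833 to 61304680), was higher by 1.77 (1.61 to 1.93), Ifng by 1.37 and the chemokine gene Ccl4 by 2.69. Gzmc stood lower, at −2.74 (−2.14 without cluster 12). Cd8a was higher by 1.24 (1.14 to 1.33), beside the larger share of CD8 cells. Of 9 inhibitory receptor and exhaustion genes 4 were higher and 3 lower, with a median of 0.25 (0.14 to 0.39; 0.61 relative to all genes). Among them Lag3 was at 0.85, Pdcd1, which encodes PD-1 itself, at 0.74 and Cd200r1 at −0.81. Of 8 naive and memory genes 2 were higher and 4 lower (median −0.20, −0.40 to −0.02; 0.16 relative to all genes), with Bach2 at −2.29, Cd27 at 1.27 and Klf2 at 0.70. The activation list had 1 of 10 members higher and 4 lower (median −0.24, −0.38 to −0.15; 0.12 relative to all genes), with Cd40lg at −1.53, Cd44 at −1.01 and Tnfrsf9 at 0.83. The regulatory T cell list had 3 of 7 members lower and none higher (median −0.22, −0.30 to −0.14; 0.14 relative to all genes), with Ccr8 at −2.06, Il2ra at −0.75 and Ikzf2 at −0.45. All 15 proliferation genes were lower, with a median of −0.84 (−0.95 to −0.73; −0.48 relative to all genes). Outside the lists, the highest genes were Ifitm1 (4.96), Areg (3.88), Wdr95 (2.37), Prr7 (2.19) and Spin2c (2.15). The Ifitm1 value rests on the cells left out, as T cell-like vehicle cells held 15 of its UMIs. Over all deposited cells Ifitm1 averaged 1.35 UMIs per 10,000 in anti-PD-1 and 0.904 in vehicle. The lowest were Fsbp (−4.82), Tsix (−4.49), the histone genes Hist1h2ai (−4.45) and Hist1h3b (−4.35), and Ttn (−3.63). Mitochondrially encoded genes were lower as well (median −0.77, 12 of 13 lower; −0.41 relative to all genes). Counted relative to all genes, higher and lower members numbered 11 and 2 in the cytotoxic list, 6 and 1 in the exhaustion list, 3 and 1 in the naive and memory list, 3 and 4 in the activation list, 2 and 2 in the regulatory list and 0 and 9 in the proliferation list. With equal weight for each cluster the cytotoxic median was 0.64 and the proliferation median 0.032, and without the cycling clusters Ikzf2 turned to 1.12. Of the 58 vehicle cells left without the cycling clusters, 54 were of CD4 cluster 10 and 0 of regulatory cluster 14. Over all deposited cells Gzmf, 2.28 in T cell-like cells, turned to −0.29.

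**Figure D2:**
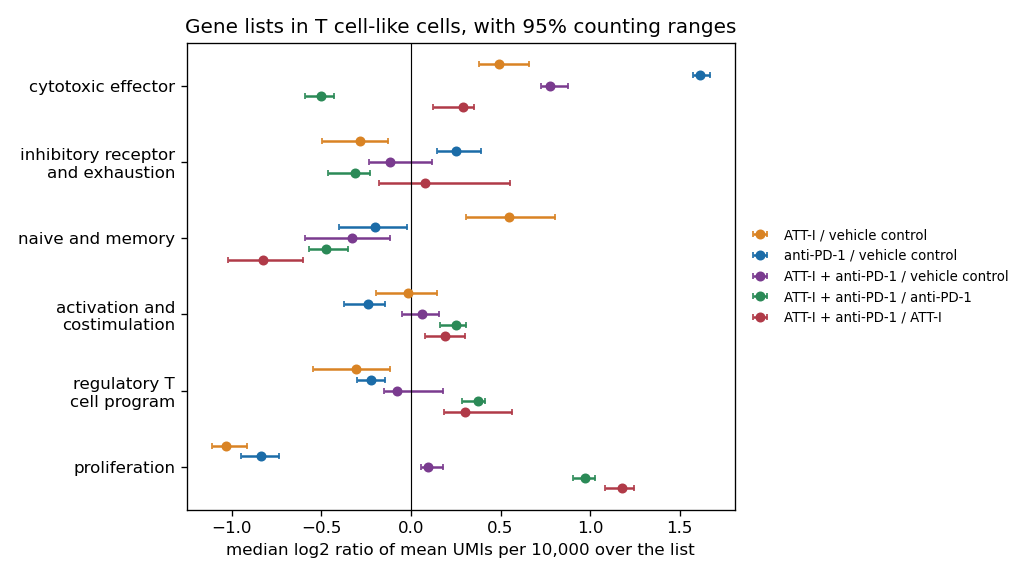
Median log2 ratio of mean UMIs per 10,000 (x axis) over the genes of each list (y axis) in T cell-like cells, 1 point per comparison, with 95% counting ranges as bars and a line at 0. Cytotoxic genes lie farthest right for anti-PD-1 against vehicle (1.61), and proliferation genes lie right of 0 for the combination against anti-PD-1 (0.97) and left of 0 for ATT-I against vehicle (−1.03).

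For ATT-I alone, set against vehicle, cytotoxic and naive and memory genes were both higher. In the cytotoxic list 8 of 13 members were higher and 1 lower (median 0.49, 0.38 to 0.66; 0.84 relative to all genes). Gzma was higher by 1.78 (1.54 to 2.02; 2.59 without cluster 12), and the chemokine genes Ccl4 and Ccl3 by 1.59 and 1.36 (0.98 and 0.76 without cluster 13, which held 4 ATT-I cells and no vehicle cell), while Gzmb was at −0.02 (−0.14 to 0.09; 0.25 without cluster 12), Prf1 at 0.28 and Ifng at 0.49. In the naive and memory list 6 of 9 were higher and 2 lower (median 0.55, 0.31 to 0.81; 0.90 relative to all genes). Ccr7, a lymph node homing receptor, was higher by 2.45 (1.82 to 3.12) and Klf2, a transcription factor of quiescent T cells, by 1.42, with Bach2 at −1.33. Of 9 exhaustion genes 2 were higher and 4 lower (median −0.28, −0.50 to −0.13; 0.065 relative to all genes), with Havcr2 (TIM-3) at −0.95, Tigit at −0.82 (−1.79 to 0.09), Cd200r1 at −0.78 and Pdcd1 at 0.52. The activation list had 1 of 10 higher and 4 lower (median −0.019, −0.19 to 0.14; 0.33 relative to all genes), with Cd44 at −0.64, Il2ra at −0.62 and Nr4a1 at 0.62. Of the 7 regulatory T cell genes 3 were lower (median −0.31, −0.55 to −0.12; 0.043 relative to all genes), with Ikzf2 at −0.63 and Ccr8 at −0.45 (−1.07 to 0.16). Proliferation genes were lower in 14 of 15 members (median −1.03, −1.11 to −0.92; −0.69 relative to all genes). Cd8a stood at 0.31. The highest genes outside the lists were Dcn (4.35, 2 UMIs in vehicle, 2.35 to 7.47) and Igfbp4 (3.95, 3 UMIs in vehicle, 2.31 to 6.28), then Socs3 (2.45), Ecm1 (2.16) and Emp1 (2.04). Dcn encodes decorin, a matrix protein of fibroblasts, and summed fibroblast markers were at 0.661 UMIs per 10,000 in ATT-I against 0.0213 in vehicle. The lowest were Tyrobp (−4.88), Map2 (−3.98), Gas2l3 (−3.78), Arhgap21 (−3.60) and Fsbp (−3.59). Tissue dissociation and stress genes were higher in 8 of 11 members (median 0.61, 0.47 to 0.74; 0.96 relative to all genes), and the 4 haemoglobin genes had a median of 8.46. Set against the all-gene shift, the activation list had 5 members higher and 0 lower, the regulatory list 2 and 0, the exhaustion list 2 and 3, the naive and memory list 7 and 1, the cytotoxic list 11 and 1 and the proliferation list 0 and 11. With equal weight per cluster the naive and memory median turned to −0.37, the cytotoxic median was 0.16 and the proliferation median −0.15. Leaving out the cycling clusters gave a cytotoxic median of 0.99 and turned Ikzf2 to 0.90. The vehicle cells then left were mostly of CD4 cluster 10 (54 of 58).

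The combination was compared with vehicle to describe both treatments together. Cytotoxic genes were higher: 9 of 13 members higher and 2 lower, median 0.78 (0.72 to 0.88; 0.92 relative to all genes). Ccl4 was higher by 3.19 and Ccl3 by 2.17, Prf1 by 1.18, Gzmb by 0.80 (0.72 to 0.88), Ifng by 0.78 and Cd8a by 0.81, and Gzmc was at −1.90 (−1.18 without cluster 12). Of 9 naive and memory genes 2 were higher and 5 lower (median −0.33, −0.59 to −0.11; −0.18 relative to all genes), with Ccr7 at 3.48, Lef1 at −1.88 and S1pr1 at −1.06. The exhaustion list had 2 of 9 members higher and 2 lower (median −0.12, −0.24 to 0.12; 0.028 relative to all genes), with Cd200r1 at −1.10, Tigit at −0.76, Lag3 at 0.52 and Pdcd1 at 0.22. Of 10 activation genes 2 were higher and 3 lower (median 0.061, −0.05 to 0.15; 0.21 relative to all genes): Nr4a1, an early gene of T cell receptor signalling, was at 1.61 and Tnfrsf9 (4-1BB) at 0.78, with Cd40lg at −0.94. The regulatory T cell list had 2 of 7 higher and 2 lower (median −0.076, −0.15 to 0.18; 0.071 relative to all genes), with Tnfrsf18 at −0.62, Ccr8 at −0.39 (−0.89 to 0.12) and Ctla4 at 0.36. Proliferation genes differed little, with 3 of 15 higher and none lower (median 0.094; 0.24 relative to all genes), and turned to −0.24 with equal cluster weights. Members higher and lower than the all-gene shift numbered 10 and 2 (cytotoxic), 2 and 4 (naive and memory), 3 and 2 (exhaustion), 3 and 2 (activation), 3 and 1 (regulatory) and 6 and 0 (proliferation). Areg (3.65), Mid1 (3.08), Exph5 (2.33), Rasd1 (2.24) and Lcn4 (2.20) were highest outside the lists. Tyrobp (−8.03, 1 UMI in the combination, −13.34 to −5.54), Klrb1c (−6.59, 3 UMIs, −8.89 to −5.01; −3.55 without cluster 12), Krt10 (−3.32), Sulf2 (−3.17) and Slc2a9 (−3.14) were lowest. Tissue dissociation and stress genes were higher in 6 of 12 members and lower in 1 (median 0.38, 0.27 to 0.42; 0.53 relative to all genes). Over all deposited cells Gzmb and Prf1 turned to −0.068 and −0.24. Without cluster 13, which held 8 combination cells and no vehicle cell, Ccl4 was at 1.02 and Ccl3 at 1.09. Without the cycling clusters the naive and memory median turned to 0.19, the regulatory median to 0.62 and Ccr8 to 0.39. Of the 58 vehicle cells then left, 54 were of CD4 cluster 10.

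Adding ATT-I to anti-PD-1 is described by the combination against anti-PD-1. Proliferation genes were higher in all 15 members (median 0.97, 0.91 to 1.03; 0.80 relative to all genes), above all 10000 random lists. Cytotoxic genes were lower in 9 of 14 members and higher in 5 (median −0.50, −0.59 to −0.43; −0.68 relative to all genes). Ccl5 was at −1.90 (−1.94 to −1.86), Gzmk at −0.90, Gzmb at −0.79 (−0.84 to −0.74), Prf1 at −0.59, Ifng at −0.59 and Cd8a at −0.42, and Xcl1, a chemokine gene for cross-presenting dendritic cells, was higher by 1.63. Of 9 exhaustion genes 1 was higher and 4 lower (median −0.31, −0.46 to −0.23; −0.49 relative to all genes), with Cd160 at −0.89, Entpd1 (CD39) at −0.80, Pdcd1 at −0.53 and Tox at 0.69. Of 9 naive and memory genes 3 were higher and 5 lower (median −0.47, −0.57 to −0.35; −0.65 relative to all genes): Ccr7 was at 2.40, Bach2 at 1.96 and Lef1 at −1.29. The activation list had 4 of 10 higher and 1 lower (median 0.25, 0.16 to 0.31; 0.076 relative to all genes), with Nr4a1 at 1.87, Cd44 at 1.07 and Il2ra at 1.05. The regulatory T cell list had 4 of 7 higher and 1 lower (median 0.38, 0.28 to 0.41; 0.20 relative to all genes), with Ccr8 at 1.67 and Tnfrsf18 at −0.39. The highest genes outside the lists were Hist1h2ai (4.28), Tsix (4.00), Exph5 (3.99), Hist1h2ab (3.80) and Lad1 (3.75), and the lowest Fcer1g (−3.64), Filip1 (−3.48), Epdr1 (−2.47), Cd7 (−2.39) and B4galt7 (−2.06). Mitochondrially encoded genes were higher in 12 of 13 members (median 0.72; 0.55 relative to all genes). Once the all-gene shift is taken off, higher and lower members were 4 and 9 (cytotoxic), 1 and 7 (exhaustion), 2 and 5 (naive and memory), 4 and 3 (activation), 2 and 2 (regulatory) and 15 and 0 (proliferation). With equal weight per cluster the proliferation median turned to −0.44. These weights kept clusters 0, 3, 7, 10 and 13 alone. The 5 combination cells of cluster 7 then weighed as much as the 95 of cluster 0. Without the cycling clusters the proliferation median was 0.11, and the naive and memory median turned to 0.032 and Tnfrsf18 to 0.22. Summarised by its mean, the naive and memory list turned to 0.039, and the cytotoxic list was −0.21.

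Inside the CD8 class alone, 107 combination cells against 5933 anti-PD-1 cells were compared by the same lists. The cytotoxic median was −0.51 (10 of 14 lower, 3 higher), with Ccl5 at −1.98, Ccl4 at −1.50, Gzmb at −0.59, Prf1 at −0.44, Ifng at −0.60 and Tnf at 1.43. The exhaustion median was −0.37 (6 of 9 lower, 2 higher), with Cd160 at −0.93, Pdcd1 at −0.68, Ctla4 at 0.90 and Tox at 0.68. The naive and memory median was −0.24 (4 of 9 lower, 2 higher), with Bach2 at 2.03 and Lef1 at −1.43. Activation genes had a median of 0.63 (5 of 9 higher, 1 lower), with Nr4a1 at 2.86, Il2ra at 1.48 and Cd44 at 1.01. The activation median was 0.12 without a minimum share of cells and 0.38 at a minimum of 5%. Regulatory T cell genes had a median of 0.71 (4 of 5 higher, 1 lower), with Tnfrsf18 at −0.74. All 15 proliferation genes were higher (median 1.22). The median over all genes was 0.18, and relative to it the 6 medians were −0.69, −0.55, −0.42, 0.45, 0.54 and 1.04 in that order, with 2 and 10, 2 and 7, 2 and 5, 5 and 1, 3 and 1, and 15 and 0 members higher and lower. Outside the lists Mroh2a (5.02), Ecm2 (4.95), Hist1h2ai (4.67), Exph5 (4.49) and Hist1h2ab (4.25) were highest, and Fcer1g (−5.29), Tcp11l2 (−4.57, 2 UMIs in the combination, −7.62 to −2.71), Slfn5 (−3.58), Filip1 (−3.33) and Kdm5b (−3.10) lowest. Cd8a was at −0.38. Ccr7, at 2.11, turned to −1.46 when cells whose 1-UMI values had been set to 0 were left out. Equal cluster weights left cluster 0 alone, where the proliferation median was −0.043 and the naive and memory median 0.17.

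Against ATT-I alone, the combination had lower naive and memory genes and higher proliferation genes. In the naive and memory list 6 of 9 members were lower and 2 higher (median −0.83, −1.02 to −0.60; −1.02 relative to all genes), with Klf2 at −1.96, S1pr1, the receptor for exit from tissue, at −1.61 and Lef1 at −1.38. All 15 proliferation genes were higher (median 1.18, 1.08 to 1.24; 0.98 relative to all genes). Of 13 cytotoxic genes 5 were higher and 3 lower (median 0.29, 0.12 to 0.35; 0.093 relative to all genes), with Ccl4 at 1.60, Xcl1 at 1.05, Prf1 at 0.89, Gzmb at 0.82, Ifng at 0.29 and Ccl5 at −0.99. The exhaustion list had 4 of 9 higher and 2 lower (median 0.080, −0.18 to 0.55; −0.11 relative to all genes), with Havcr2 at 0.69, Ctla4 at 0.64, Cd160 at −0.72 and Pdcd1 at −0.30. Of 10 activation genes 5 were higher and 2 lower (median 0.19, 0.08 to 0.30; −0.0056 relative to all genes), with Nr4a1 at 0.99, Il2ra at 0.91 and Cd40lg at −0.85. Of 7 regulatory T cell genes 3 were higher and 1 lower (median 0.30, 0.19 to 0.57; 0.11 relative to all genes), with Tnfrsf18 at −0.67. Cd8a was at 0.50. Map2 (4.11), Arnt2 (3.59), Arhgap21 (3.56), Phykpl (3.45) and Gas2l3 (3.22) were highest outside the lists. Igfbp4 (−7.52, 1 UMI in the combination, −12.86 to −4.97) and Dcn (−6.21, 1 UMI, −11.57 to −3.61) were lowest, then Klk1b9 (−2.43), Dhrs3 (−2.14) and Tmem176b (−2.13). Summed fibroblast markers were at 0.661 UMIs per 10,000 in ATT-I and 0.0154 in the combination. The 4 haemoglobin genes had a median of −9.88, and stress genes one of −0.17 (−0.37 relative to all genes). Against the all-gene shift, 5 cytotoxic members were higher and 5 lower, with 4 and 3 for exhaustion, 2 and 6 for naive and memory, 4 and 4 for activation, 3 and 1 for regulatory T cell and 15 and 0 for proliferation genes. Equal cluster weights turned the naive and memory median to 0.53 and brought the proliferation median to 0.12. Without cluster 13 the cytotoxic median was 0.086 and Ccl4 was at 0.045, and without the cycling clusters the cytotoxic median turned to −0.18, Map2 to −1.60, Cd8a to −0.15, Cd40lg to 0.18 and Tnfrsf18 to 0.0089.

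In CD8 cells the combination against ATT-I, 107 against 81 cells, gave a naive and memory median of −1.20 (6 of 9 lower, 2 higher), with Lef1 at −2.74, Bach2 at 2.10 and Ccr7 at 1.67. The regulatory T cell list was at 1.30 (4 of 5 higher, 1 lower) and the activation list at 0.62 (5 of 9 higher, 2 lower), through Il2ra at 1.92, Nr4a1 at 1.57, Ctla4 at 1.55, Ikzf2 at 1.30 and Icos at 1.001. The exhaustion list was at 0.48 (5 of 9 higher, 1 lower), with Tox at 1.06 and Cd160 at −1.17. The cytotoxic list was at −0.055 (4 of 14 higher, 4 lower), with Ccl5 at −1.47, Tnf at −1.03, Gzmf at 1.02, Gzmb at 0.61, Prf1 at 0.36, Ifng at −0.09, Pdcd1 at −0.18 and Cd8a at −0.02. All 15 proliferation genes were higher (median 0.98; 0.10 with equal cluster weights, which left cluster 0 alone). The median over all genes was 0.24, and relative to it the cytotoxic list was at −0.30, exhaustion 0.24, naive and memory −1.44, activation 0.38, regulatory T cell 1.06 and proliferation 0.74. Members higher and lower were then 3 and 7, 2 and 3, 2 and 6, 5 and 3, 3 and 1, and 14 and 0. Areg (6.25, 1 UMI in ATT-I, 3.76 to 11.56), Alms1 (4.48, 1 UMI, 1.93 to 9.81), Tgif2 (4.02, 2 UMIs, 2.09 to 7.11), Tiparp (3.95, 3 UMIs, 2.35 to 6.26) and Map2 (3.85, 3 UMIs, 2.24 to 6.16) were highest outside the lists. Igfbp4 (−6.00, 1 UMI in the combination, −11.40 to −3.30), Bgn (−5.47, 1 UMI, −10.93 to −2.62), Slfn5 (−4.91), Tmem176b (−4.38, 3 UMIs, −6.86 to −2.46) and Tcp11l2 (−4.29, 2 UMIs, −7.52 to −2.06) were lowest. Ratios of summed UMIs turned the exhaustion median to −0.095 and Prf1 to −0.29. Equal cluster weights left cluster 0 alone. In it the naive and memory median was 0.30, exhaustion 0.015, activation 0.20 and regulatory T cell 0.65. Without a minimum share of cells, or at 5%, the activation median was 0.21 and the regulatory median 0.82, and at 25% the naive and memory median was −0.36. Ccr7 turned to −1.90 when cells whose 1-UMI values had been set to 0 were left out.

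The combination was also set against the sum of the log2 ratios of both single treatments to vehicle. Cytotoxic genes fell short of the sum in 11 of 14 members and exceeded it in 3, with a median difference of −1.001 (−1.11 to −0.87; −1.52 relative to all genes). Their median was 0.79 in the combination and 2.07 for the sum. Naive and memory genes were below the sum in 6 of 9 members (median difference −0.79, −1.02 to −0.51; −1.30 relative to all genes). Proliferation genes were above it in all 15 (1.96, 1.81 to 2.07; 1.44 relative to all genes). Exhaustion genes (0.39, −0.20 to 0.50), activation genes (0.42, 0.08 to 0.55) and regulatory T cell genes (0.39, 0.28 to 0.64) were no farther above it than the median of all genes, 0.52. The exhaustion difference turned to −0.16 with summed UMIs and to −0.0087 with list means. The 4 libraries enter each value once and the vehicle library is shared, so these values are a description only.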

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

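The tests of the treatment as a cause of the proliferation difference, of red cells captured with T cells, and of library preparation, the check of the UMI window, the values above it and haemoglobin without cluster 3 were chosen after the values had been seen, as were the 3 patterns themselves.

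For 3 of the lymphocyte and proliferation lists, adding ATT-I went opposite ways without and with anti-PD-1 by at least 0.32 log2 each. The difference was not tested, since each value compares 1 library with 1 other. The cytotoxic median was 0.49 for ATT-I against vehicle and −0.50 for the combination against anti-PD-1. The first was 0.16 with equal cluster weights and the second −0.21 by list mean, each of the same sign but short of 0.32. The naive and memory median was 0.55 and −0.47, but the opposition is lost with equal cluster weights (−0.37 and −0.045), and the second value was 0.039 by list mean and 0.032 without the cycling clusters. The proliferation median was −1.03 and 0.97, and −0.15 and −0.44 with equal cluster weights. Regulatory T cell (−0.31 and 0.38), activation (−0.019 and 0.25) and mitochondrial medians (−0.15 and 0.72) also differed in sign, but not relative to all genes (0.043 and 0.20, 0.33 and 0.076, 0.20 and 0.55). Haemoglobin went 8.46 and −5.46, the second from 1 gene. Relative to all genes the 6 antigen presentation, proteasome and interferon lists also had opposite signs, by at least 0.32 each for the 20S core (0.34 and −0.38) and type I interferon (0.34 and −0.40), as did the exhaustion list (0.065 and −0.49). The all-gene medians were −0.35 and 0.17, so centring alone gives opposite signs to a list near 0 in both comparisons. Uncentred, signs were the same for the 20S core (−0.011 and −0.21), type I interferon (−0.013 and −0.23) and exhaustion (−0.28 and −0.31).

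Proliferation genes were higher in the combination library than in anti-PD-1. Another mix of CD4, CD8 and regulatory cells is argued against as the whole cause, since the median within CD8 cells was 1.22 (1.18 to 1.31). Another mix of states within CD8 stays open: cluster 0 held 95 of 107 combination and 1105 of 5933 anti-PD-1 CD8 cells. Equal cluster weights there left cluster 0 alone. Its median of −0.043 cannot decide this, as cluster 0 is itself a cycling cluster. A difference in UMIs per cell stays open: in cells of 5000 to 15000 UMIs the median was −0.70 (−0.91 to −0.33), the outcome written down beforehand for it, but that window kept 4 of 128 combination cells of cycling clusters (3.12%) and 36 of 65 others (55.4%), so it removes the cells in question and decides nothing. Above 15000 UMIs the median was −0.051 (−0.12 to 0.029). Thinning cells to 3000 UMIs, with shallower cells left out, gave 0.97. Thinning keeps the expected share of each gene in a cell, so that value cannot decide the question. The treatment cannot be told apart from the library either, as the median against vehicle, the other deep library, was 0.094 (0.054 to 0.18).

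Haemoglobin RNA was found in nearly every ATT-I cell. Red blood cells captured singly with T cells are argued against as the source in most cells, since 98.7% of ATT-I cells held a Hbb-bs UMI. That share is the pattern itself, so it is no separate test. Free RNA from lysed red blood cells may be the source but is not settled: cluster means of Hbb-bs differed 3.52-fold, between the bound of 3 set for free RNA and the bound of 10 set against it, and 1.67-fold without cluster 3 (21 cells). The median ATT-I cell held 6 Hbb-bs UMIs and 4 cells held over 100. No biological explanation was tested.

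Histone genes were lower in the anti-PD-1 library, by a median of 2.56 log2 against vehicle, 1.83 against ATT-I and 2.21 against the combination. Fewer cycling cells are argued against as the whole cause, because within cluster 0, a cycling cluster, the combination was still higher by 1.09 (1.01 to 1.20). The range only just clears the bound of 1 log2 set for it, and the drop from 2.21 leaves room for a part. A difference in how the library was made stays open, with 98.2% of the genes (55 of 56) lower than in each other library, and it cannot be told apart from treatment with 1 library per arm.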

How the results depend on the processing

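Alternatives chosen after the data had been seen were the first naming rule, all deposited cells, equal cluster weights, and leaving out cell cycle clusters, doublets from gene levels, cells whose 1-UMI values were set to 0, cluster 13 or cluster 12. Over class shares, list medians and named genes, the alternatives gave 2383 values within the counting range of the reported value, 855 outside it and 31 reported values of at least 0.32 log2 with the sign turned. These counts leave out the filter of 500 genes and the differences of natural logs, which turned 1 further sign. The direction of the cytotoxic median held in 16 of 16 alternatives for anti-PD-1 against vehicle (0.64 to 1.97), ATT-I against vehicle (0.16 to 0.99), the combination against vehicle (0.44 to 0.92) and the combination against anti-PD-1 (−0.86 to −0.21), differences of natural logs set aside. Those differences are on another scale, so only their sign compares. The filter of 500 genes is among the 16 but removes no cell and moved no value, so it could not turn a sign. The direction of the proliferation median held in 16 of 16 for ATT-I against vehicle (−1.25 to −0.15). Most signs turned under equal cluster weights or without the cell cycle clusters, and the cause was not tested. Without cycling clusters, CD8 cells were too few for a value (2 in vehicle, 6 in the combination). The vehicle library then kept 58 T cell-like cells, 54 of them in CD4 cluster 10 and 0 in regulatory cluster 14. Values against vehicle without the cycling clusters therefore compare different mixes of T cell classes and do not isolate the cell cycle. They are among the 16 alternatives. Depth limits low genes most in the libraries of 155, 297 and 199 cells. Leaving out a replicate is not possible with 1 library per arm. No paired analysis was possible because each arm has 1 library. For class shares, lymphocyte lists and the proliferation list, values outside the counting range or with the sign turned follow, and for the other lists and named genes those with the sign turned. Leaving out cluster 12 moved no list median outside its range and turned no reported value of at least 0.32 log2. Comparisons are written as arm/reference, and T cell-like cells are meant unless CD8 cells are named.

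Using ratios of summed UMIs, cytotoxic medians were 0.36 for ATT-I/vehicle, 1.31 for anti-PD-1/vehicle, 0.62 for combination/vehicle and −0.75 for the combination minus the sum. Exhaustion medians were 0.45 for anti-PD-1/vehicle, −0.49 for combination/anti-PD-1 and −0.16 for the combination minus the sum (reversed from 0.39), and naive and memory medians were −0.41 for anti-PD-1/vehicle and −0.30 for combination/anti-PD-1. Activation medians were 0.18 for ATT-I/vehicle and 0.15 for combination/anti-PD-1, and regulatory medians were −0.44 for anti-PD-1/vehicle, 0.25 for combination/anti-PD-1 and 0.81 for the combination minus the sum. Proliferation medians were −0.67 for ATT-I/vehicle, −0.067 for combination/vehicle, 0.77 for combination/anti-PD-1 and 0.72 for combination/ATT-I. In CD8 cells cytotoxic medians were −0.65 for combination/anti-PD-1 and −0.21 for combination/ATT-I, and the exhaustion median was −0.095 for combination/ATT-I (reversed from 0.48). The regulatory median was 0.56 for combination/anti-PD-1, and proliferation medians were 0.81 for combination/anti-PD-1 and 0.59 for combination/ATT-I, in CD8 cells. The interferon-gamma median was 0.16 for combination/ATT-I (reversed from −0.36), in CD8 cells. This choice also reversed Prf1 to −0.29 for combination/ATT-I in CD8 cells, from 0.36.

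After thinning to 3000 UMIs, cytotoxic medians were 0.37 for ATT-I/vehicle, 1.57 for anti-PD-1/vehicle, 0.70 for combination/vehicle and −0.34 for combination/anti-PD-1. Exhaustion medians were 0.41 for anti-PD-1/vehicle and 0.13 for combination/vehicle, and naive and memory medians were −0.64 for combination/anti-PD-1, −0.58 for combination/ATT-I and −0.46 for the combination minus the sum. Activation medians were 0.096 for combination/anti-PD-1 and 0.53 for combination/ATT-I, and regulatory medians were −0.16 for combination/vehicle and 0.70 for combination/ATT-I. The cytotoxic median was −0.17 for combination/ATT-I, and the exhaustion median was −0.23 for combination/anti-PD-1, in CD8 cells. Naive and memory medians were −0.60 for combination/anti-PD-1 and −1.40 for combination/ATT-I, and the activation median was 0.91 for combination/anti-PD-1, in CD8 cells. The proliferation median was 1.12 for combination/ATT-I, in CD8 cells.

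Summarised by list means, cytotoxic means were 1.01 for anti-PD-1/vehicle, −0.21 for combination/anti-PD-1 and −0.73 for the combination minus the sum, and the exhaustion mean was −0.0087 for the combination minus the sum (reversed from 0.39). Naive and memory means were −0.045 for combination/vehicle, 0.039 for combination/anti-PD-1 (reversed from −0.47), −0.58 for combination/ATT-I and −0.49 for the combination minus the sum, and the activation mean was 0.42 for combination/anti-PD-1. Regulatory means were −0.46 for anti-PD-1/vehicle, 0.43 for combination/anti-PD-1 and 0.74 for the combination minus the sum, and proliferation means were −1.003 for anti-PD-1/vehicle and 1.15 for combination/anti-PD-1. In CD8 cells the cytotoxic mean was −0.35 for combination/anti-PD-1, and the exhaustion mean was −0.23 for combination/anti-PD-1. The naive and memory mean was 0.074 for combination/anti-PD-1, and regulatory means were 0.55 for combination/anti-PD-1 and 0.86 for combination/ATT-I, in CD8 cells. The proliferation mean was 1.44 for combination/anti-PD-1, in CD8 cells.

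Without a minimum share of cells, regulatory medians were −0.13 for anti-PD-1/vehicle and 0.24 for combination/anti-PD-1. Activation medians were 0.12 for combination/anti-PD-1 and 0.21 for combination/ATT-I, and regulatory medians were 0.81 for combination/anti-PD-1 and 0.82 for combination/ATT-I, in CD8 cells.

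At a minimum share of 5%, in CD8 cells activation medians were 0.38 for combination/anti-PD-1 and 0.21 for combination/ATT-I, and regulatory medians were 0.81 for combination/anti-PD-1 and 0.82 for combination/ATT-I.

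At a minimum share of 25%, the exhaustion median was 0.47 for anti-PD-1/vehicle, and the naive and memory median was 0.012 for anti-PD-1/vehicle. The activation median was 0.42 for combination/ATT-I, and the regulatory median was −0.34 for anti-PD-1/vehicle. The cytotoxic median was −0.58 for combination/anti-PD-1, and naive and memory medians were −0.095 for combination/anti-PD-1 and −0.36 for combination/ATT-I, in CD8 cells.

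With totals without mitochondrial and ribosomal genes, the cytotoxic median was 1.72 for anti-PD-1/vehicle, and activation medians were 0.15 for ATT-I/vehicle and 0.072 for combination/ATT-I. Regulatory medians were −0.14 for anti-PD-1/vehicle and 0.17 for combination/ATT-I, and proliferation medians were −0.89 for ATT-I/vehicle and 1.07 for combination/ATT-I. In CD8 cells cytotoxic medians were −0.61 for combination/anti-PD-1 and −0.18 for combination/ATT-I, and the activation median was 0.51 for combination/anti-PD-1. The regulatory median was 0.59 for combination/anti-PD-1, and proliferation medians were 1.15 for combination/anti-PD-1 and 0.83 for combination/ATT-I, in CD8 cells.

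After centring on the all-gene median, cytotoxic medians were 0.84 for ATT-I/vehicle, 1.97 for anti-PD-1/vehicle, 0.92 for combination/vehicle, −0.68 for combination/anti-PD-1 and 0.093 for combination/ATT-I. Exhaustion medians were 0.065 for ATT-I/vehicle, 0.61 for anti-PD-1/vehicle and −0.49 for combination/anti-PD-1. Naive and memory medians were 0.90 for ATT-I/vehicle, 0.16 for anti-PD-1/vehicle and −0.65 for combination/anti-PD-1. Activation medians were 0.33 for ATT-I/vehicle, 0.12 for anti-PD-1/vehicle, 0.21 for combination/vehicle, 0.076 for combination/anti-PD-1 and −0.0056 for combination/ATT-I. Regulatory medians were 0.043 for ATT-I/vehicle, 0.14 for anti-PD-1/vehicle, 0.20 for combination/anti-PD-1 and 0.11 for combination/ATT-I. Proliferation medians were −0.69 for ATT-I/vehicle, −0.48 for anti-PD-1/vehicle, 0.24 for combination/vehicle, 0.80 for combination/anti-PD-1 and 0.98 for combination/ATT-I. The interferon-gamma median was 0.0076 for anti-PD-1/vehicle (reversed from −0.35). Cytotoxic medians were −0.69 for combination/anti-PD-1 and −0.30 for combination/ATT-I, and naive and memory medians were −0.42 for combination/anti-PD-1 and −1.44 for combination/ATT-I, in CD8 cells. The activation median was 0.45 for combination/anti-PD-1, and regulatory medians were 0.54 for combination/anti-PD-1 and 1.06 for combination/ATT-I, in CD8 cells. Proliferation medians were 1.04 for combination/anti-PD-1 and 0.74 for combination/ATT-I, in CD8 cells.

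As differences of mean natural log values, cytotoxic differences were 0.055 for ATT-I/vehicle, 0.30 for anti-PD-1/vehicle, 0.21 for combination/vehicle, −0.15 for combination/anti-PD-1 and −0.21 for the combination minus the sum. Exhaustion differences were −0.057 for ATT-I/vehicle, 0.076 for anti-PD-1/vehicle and −0.033 for combination/anti-PD-1. Naive and memory differences were 0.080 for ATT-I/vehicle, −0.042 for combination/vehicle, −0.034 for combination/anti-PD-1, −0.11 for combination/ATT-I and −0.057 for the combination minus the sum. Regulatory differences were −0.072 for ATT-I/vehicle and 0.22 for combination/anti-PD-1. Proliferation differences were −0.35 for ATT-I/vehicle, −0.33 for anti-PD-1/vehicle, 0.39 for combination/anti-PD-1 and 0.44 for combination/ATT-I. In CD8 cells cytotoxic differences were −0.14 for combination/anti-PD-1 and 0.13 for combination/ATT-I, and the exhaustion difference was −0.044 for combination/anti-PD-1. Naive and memory differences were 0.00024 for combination/anti-PD-1 and −0.051 for combination/ATT-I, and activation differences were 0.17 for combination/anti-PD-1 and 0.27 for combination/ATT-I, in CD8 cells. Regulatory differences were 0.21 for combination/anti-PD-1 and 0.19 for combination/ATT-I, and proliferation differences were 0.74 for combination/anti-PD-1 and 0.55 for combination/ATT-I, in CD8 cells. The interferon-gamma difference was 0.0053 for combination/ATT-I (reversed from −0.36), in CD8 cells.

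Over all deposited cells, cytotoxic medians were 0.27 for ATT-I/vehicle, 1.13 for anti-PD-1/vehicle, 0.44 for combination/vehicle, 0.36 for combination/ATT-I and −0.79 for the combination minus the sum. The exhaustion median was 0.71 for the combination minus the sum, and naive and memory medians were 0.98 for ATT-I/vehicle, −1.26 for combination/ATT-I and −1.10 for the combination minus the sum. Activation medians were −0.21 for ATT-I/vehicle, 0.31 for combination/anti-PD-1, 0.42 for combination/ATT-I and 0.61 for the combination minus the sum. Regulatory medians were −0.55 for ATT-I/vehicle, 0.42 for combination/anti-PD-1 and 0.71 for the combination minus the sum. Proliferation medians were −1.25 for ATT-I/vehicle, 0.24 for combination/vehicle, 1.11 for combination/anti-PD-1 and 1.47 for combination/ATT-I. This choice also reversed Gzmf to −0.29 for anti-PD-1/vehicle, from 2.28, Gzmb to −0.068 for combination/vehicle, from 0.80 and Prf1 to −0.24 for combination/vehicle, from 1.18.

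Under equal cluster weights, cytotoxic medians were 0.16 for ATT-I/vehicle, 0.64 for anti-PD-1/vehicle, 0.49 for combination/vehicle and 0.027 for combination/ATT-I, and the exhaustion median was −0.53 for combination/anti-PD-1. Naive and memory medians were −0.37 for ATT-I/vehicle (reversed from 0.55), −0.44 for anti-PD-1/vehicle, −0.045 for combination/anti-PD-1 and 0.53 for combination/ATT-I (reversed from −0.83). Activation medians were 0.13 for combination/anti-PD-1 and 0.58 for combination/ATT-I. Regulatory medians were −0.75 for ATT-I/vehicle, −0.47 for anti-PD-1/vehicle, −0.17 for combination/vehicle, 0.64 for combination/anti-PD-1 and 0.71 for combination/ATT-I. Proliferation medians were −0.15 for ATT-I/vehicle, 0.032 for anti-PD-1/vehicle (reversed from −0.84), −0.24 for combination/vehicle, −0.44 for combination/anti-PD-1 (reversed from 0.97) and 0.12 for combination/ATT-I. In T cell-like cells these weights left out each cluster with under 5 cells in either library. In CD8 cells only cluster 0 had at least 5 cells in both libraries, so the values that follow come from cluster 0 alone. In CD8 cells the cytotoxic median was 0.069 for combination/ATT-I, and the exhaustion median was 0.015 for combination/ATT-I. Naive and memory medians were 0.17 for combination/anti-PD-1 and 0.30 for combination/ATT-I (reversed from −1.20), and the activation median was 0.20 for combination/ATT-I, in CD8 cells. Regulatory medians were 0.52 for combination/anti-PD-1 and 0.65 for combination/ATT-I, and proliferation medians were −0.043 for combination/anti-PD-1 (reversed from 1.22) and 0.10 for combination/ATT-I, in CD8 cells. The interferon-gamma median was 1.12 for combination/ATT-I (reversed from −0.36), and the type I interferon median was 1.05 for combination/ATT-I (reversed from −0.74), in CD8 cells.

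Without the cell cycle clusters, cytotoxic medians were 0.99 for ATT-I/vehicle, 1.73 for anti-PD-1/vehicle, 0.90 for combination/vehicle, −0.86 for combination/anti-PD-1 and −0.18 for combination/ATT-I. Exhaustion medians were −0.11 for ATT-I/vehicle and −0.16 for combination/anti-PD-1, and naive and memory medians were 0.19 for combination/vehicle (reversed from −0.33), 0.032 for combination/anti-PD-1 (reversed from −0.47) and −0.25 for combination/ATT-I. Activation medians were −0.056 for anti-PD-1/vehicle, 0.34 for combination/vehicle, 0.40 for combination/anti-PD-1 and 0.51 for combination/ATT-I. Regulatory medians were 0.62 for combination/vehicle, 0.42 for combination/anti-PD-1 and 0.78 for combination/ATT-I. Proliferation medians were −0.037 for anti-PD-1/vehicle, −0.30 for combination/vehicle, 0.11 for combination/anti-PD-1 and 0.86 for combination/ATT-I, and the interferon-gamma median was 0.22 for anti-PD-1/vehicle (reversed from −0.35). It also reversed Ikzf2 to 0.90 for ATT-I/vehicle, from −0.63, Ikzf2 to 1.12 for anti-PD-1/vehicle, from −0.45, Ccr8 to 0.39 for combination/vehicle, from −0.39, Tnfrsf18 to 0.22 for combination/anti-PD-1, from −0.39, Cd40lg to 0.18 for combination/ATT-I, from −0.85, Tnfrsf18 to 0.0089 for combination/ATT-I, from −0.67, Cd8a to −0.15 for combination/ATT-I, from 0.50 and Map2 to −1.60 for combination/ATT-I, from 4.11.

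Without cells whose 1-UMI values were set to 0, cytotoxic medians were 0.91 for combination/vehicle and −0.62 for combination/anti-PD-1, and activation medians were 0.34 for combination/anti-PD-1, 0.35 for combination/ATT-I and 0.65 for the combination minus the sum. Regulatory medians were −0.33 for anti-PD-1/vehicle and 0.44 for combination/anti-PD-1, and proliferation medians were −0.65 for anti-PD-1/vehicle, 0.80 for combination/anti-PD-1 and 1.06 for combination/ATT-I. For CD8 cells the cytotoxic median was −0.44 for combination/anti-PD-1, and the exhaustion median was −0.27 for combination/anti-PD-1. The regulatory median was 0.85 for combination/anti-PD-1, in CD8 cells. This choice also reversed Ccr7 to −1.46 for combination/anti-PD-1 in CD8 cells, from 2.11 and Ccr7 to −1.90 for combination/ATT-I in CD8 cells, from 1.67.

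Without cluster 13, cytotoxic medians were −0.62 for combination/anti-PD-1 and 0.086 for combination/ATT-I.

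At a resolution of 0.5, the CD8 share was 39.3% in anti-PD-1, and the CD4 shares were 6.03% in anti-PD-1 and 19.2% in ATT-I. At a resolution of 2, the CD8 share was 50.8% in anti-PD-1, and the regulatory share was 8.54% in the combination. With 15 principal components, the CD8 share was 48.6% in anti-PD-1, and the CD4 shares were 14.4% in anti-PD-1 and 44.4% in ATT-I, and the NK share was 0.350% in anti-PD-1. With 50 principal components, the CD8 share was 50.1% in anti-PD-1, and the CD4 share was 10.99% in anti-PD-1. With fixed-list genes kept for clustering, the CD8 share was 52.4% in anti-PD-1, and the NK shares were 0% in vehicle, 0% in anti-PD-1, 0% in ATT-I and 0% in the combination. Classed cell by cell from the highest marker mean, the CD8 shares were 71.7% in anti-PD-1 and 37.4% in ATT-I, and the CD4 shares were 7.33% in anti-PD-1 and 14.6% in the combination, and the regulatory shares were 24.5% in vehicle, 17.9% in anti-PD-1, 22.2% in ATT-I and 24.1% in the combination, and the NK shares were 2.44% in anti-PD-1 and 5.39% in ATT-I. Under the first naming rule, the CD8 share was 60.0% in anti-PD-1.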

Other observations

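The genes and lists read in this part were chosen after the data had been seen, except the stress, mitochondrial and haemoglobin lists and the cell type markers, and no explanation was tested.

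Antigen presentation genes could be read in T cell-like cells. The class I list had medians of −0.11 for ATT-I, −0.069 for anti-PD-1 and −0.11 for the combination, each against vehicle, and 0.13 and 0.018 for the combination against anti-PD-1 and ATT-I. In the same order, immunoproteasome and PA28 genes were at 0.17, 0.44, 0.14, −0.14 and 0.089. Genes of the 20S proteasome core were at −0.011, 0.34, 0.13, −0.21 and 0.12, and of the 19S regulator at −0.028, 0.18, 0.16, 0.055 and 0.21. Interferon-gamma response genes were at −0.035, −0.35, −0.31, 0.0053 and 0.031, and type I interferon genes at −0.013, −0.099, −0.12, −0.23 and −0.31. Within the CD8 class the combination against ATT-I gave −0.36 for interferon-gamma and −0.74 for type I interferon genes, which equal cluster weights turned to 1.12 and 1.05. Against anti-PD-1 they were at 0.22 and −0.26. Relative to the median of all genes, and in the same order, class I genes were at 0.24, 0.29, 0.033, −0.045 and −0.18, immunoproteasome genes at 0.52, 0.80, 0.29, −0.31 and −0.11, and 20S genes at 0.34, 0.71, 0.28, −0.38 and −0.077. Among random lists of matched expression, class I medians stood at percentiles 24.7, 28.4, 4.495, 74.55 and 34.6. Against vehicle, class I genes were thus not high among genes of matched expression. Immunoproteasome medians stood at percentiles 64.4, 83.8, 66.8, 43.7 and 64.85, and 20S medians at 75.8, 96.4, 90.1, 10.0 and 42.1. Relative to all genes, 19S genes were at 0.32, 0.55, 0.31, −0.12 and 0.013, interferon-gamma genes at 0.31, 0.0076, −0.16, −0.17 and −0.16, and type I interferon genes at 0.34, 0.26, 0.023, −0.40 and −0.50. Their percentiles among matched random lists were 95.1, 98.0, 99.0, 30.2 and 45.6 for 19S genes. Interferon-gamma genes were at percentiles 92.25, 32.15, 2.535, 23.2 and 12.2, and type I interferon genes at 93.2, 72.9, 40.3, 2.855 and 0.14. The interferon-gamma median for anti-PD-1 against vehicle also turned to 0.22 without the cycling clusters.

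Dissociation and stress genes had medians of 0.61, 0.32, 0.38, 0.19 and −0.17 in the same order, and mitochondrially encoded genes −0.15, −0.77, −0.0083, 0.72 and 0.19. Relative to all genes these were 0.96, 0.68, 0.53, 0.019 and −0.37 for stress and 0.20, −0.41, 0.14, 0.55 and −0.0056 for mitochondrial genes. Over all cells, Mki67 averaged 6.97 UMIs per 10,000 in vehicle, 1.39 in anti-PD-1, 1.30 in ATT-I and 7.47 in the combination. Tsix averaged 4.01, 0.185, 0.401 and 3.02, and Xist 21.7, 11.04, 12.7 and 16.8, in that order.

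Hbb-bs UMIs were found in 5.81% of vehicle, 29.9% of anti-PD-1, 98.7% of ATT-I and 2.51% of combination cells. The 4 haemoglobin genes had a median of 8.46 for ATT-I against vehicle and −9.88 for the combination against ATT-I. With anti-PD-1, 1 of the 4 passed the minimum, at 3.64 against vehicle and −5.46 for the combination against anti-PD-1. Summed erythroid markers averaged 0.0901, 0.983, 30.5 and 0.0307 UMIs per 10,000 in that order, fibroblast markers 0.0213, 0.216, 0.661 and 0.0154, and monocyte or macrophage markers 9.53, 11.3, 6.80 and 9.88. Gm42418 averaged 88.4, 22.5, 70.8 and 72.9.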
